A study of Drosophila melanogaster with 2 samples.

How the data were processed

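Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole wandering larvae of the third instar, both sexes pooled, from a Drosophila melanogaster line in which an intronic GFP exon (a MiMIC insertion) makes the CrebA gene produce a CrebA-eGFP fusion protein. CrebA is a bZIP transcription factor of the CREB3 family. Per the labels, chromatin was sheared by sonication and precipitated with an antibody against GFP, so the peaks report the tagged protein and whatever DNA it was held near. The labels give 1 group of 2 biological replicates, numbered 4 and 2, and no second condition, so the study compares no groups.

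The authors deposited peak lists in narrowPeak format on the dm6 and dm3 assemblies. Per the deposited notes, a relaxed list of peaks and background was called for each replicate and for the pooled alignments, against a control, and the optimal list was then thresholded by the irreproducible discovery rate (IDR), a method that compares the ranks of peaks between replicates. The aligner, the peak caller and the IDR cutoff are not given in the sources used here, nor whether duplicate or multiply mapped reads were removed. The signal of a peak is the authors' deposited value and was used to rank and describe peaks within a list. Its scaling to depth is not stated. The deposited −log10 q-value of each peak reached the same ceiling of 3.12 for the strongest pooled dm6 peaks, so peaks were ranked by signal. Read counts were not analysed here, so depth is unknown and no interval that needs it is given. Intervals on shares of peaks or genes cover counting error only, and neighbouring peaks and divergent genes are not independent. The pooled and replicate relaxed lists each held 29999 peaks on dm6, which fixes their length whatever the signal. Of the 2238 optimal dm6 peaks, 2237 were among the 2238 strongest pooled peaks by signal, so the optimal list acts as a signal cutoff on the pooled peaks. On dm3 all 3699 optimal peaks were the strongest 3699 pooled peaks. Printed coordinates are dm6 and none were converted. The dm3 lists gave counts, signals, the cover of the mitochondrial genome and summit matches to other dm3 lists, and entered no gene or motif comparison. All dm6 peaks ended inside the Release 6 sequences.

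Genes and transcription start sites came from the Ensembl release 115 annotation (BDGP6.54), leaving out transposable elements, and sequence from the Release 6 RefSeq assembly. A promoter peak is an optimal peak whose summit lies within 500 bp of any annotated start site. A peak near several genes counts for each: of the 659 peaks assigned to protein-coding genes, 55 went to 2 or more genes. Locations were assigned in the order promoter, 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic. Peak sets were compared with sets rotated along each chromosome arm by a random distance (1000 rotations, one-sided permutation p, smallest possible value 0.000999). The rotated shares of each location use 20 rotations, and the overlap of peak intervals used 100.

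The gene lists, the 12 motifs and the tests of this paragraph were fixed before the data were examined, except where stated for peak signals. Each of 15 lists, and the early secretory list that joins 3 of them, was tested by a two-sided Fisher's exact test for promoter peaks against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 16 lists. Of the listed names, 3 (Gtp-bp, n-syb and dp) matched no symbol or unique synonym and 7 were matched as synonyms. The 3 were left out, so a gene annotated under another name may be missing from its list. The housekeeping comparison joins the proteasome, cytoplasmic ribosome and mitochondrial respiration lists. Peak signals of 2 sets of genes were compared by the difference of medians, with an exact permutation test where a set had fewer than 10 genes and 100000 resamples otherwise. The plan held this comparison for secretory against housekeeping genes only, with 100000 resamples. The exact version and the comparison with other nuclear genes were not in the plan. Each of 12 motifs was sought on both strands within 100 bp of the summit and in windows of the same width 1000 bp to either side. Exact McNemar tests compared the summit with each side, the larger p is given, and p-values were adjusted over the 12 motifs. Motif windows left the sequence at 4 peaks, which were left out. Shares carry Wilson 95% intervals, except the replicate overlap, which carries an exact binomial one.

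The genes named are CrebA, the 10 protein-coding genes with the strongest promoter peaks, up to 3 members of each list with the strongest promoter peaks, and the first 3 members in alphabetical order without one in each of the 3 early secretory lists. The first 10 places all fell on the mitochondrial genome, so the 10 strongest nuclear genes were added after their values were seen. Other genes named for small counts, a shared peak or a part of a list were also chosen after their values were seen.

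The functions were tested on simulated data. With 200 seeded promoters among 13981 genes, 100% were called. Each summit was seeded inside the promoter window, so this checks the code only. Of random lists of 79 genes, 3.2% passed an unadjusted p of 0.05, and of 40 rotated peak sets 2 did. Sites of the CREB3 motif planted at 1% of the 2234 summits (22 sites) passed the motif test in 10 of 10 draws, and sites planted at 0.5% (11 sites) in 0 of 10. These draws were judged at an unadjusted p of 0.05.

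Alternatives covered the peak threshold, the promoter window, the start sites used, the overlap rule, the assembly, the motif window and background, and each replicate alone, for which the 2238 strongest peaks of the other replicate replaced the optimal list. Added after the data were seen were the removal of mitochondrial peaks, the removal from the housekeeping genes of 21 respiration genes whose symbol ends in L (with or without a digit) and of 16 ribosomal genes in a and b pairs, rotation within the span of the pooled peaks, and 10000 random lists matched on each gene's number of distinct start sites (genes with 8 or more in 1 class, two-sided permutation p). The motifs at secretory promoter peaks, the peaks near tRNA and other non-coding genes, the optimal peaks missing from a replicate's list and the cover and signal of mitochondrial peaks were also looked at only then. The number of start sites had been set as an explanation to weigh for the ecdysone response list too; its values stand with that list in place of a separate weighing. The test against matched lists was first run one-sided, and the larger two-sided p is given. For the individual lists other than the early secretory one, the 1000 strongest peaks and the gene 5′ ends were also added then. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.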

Results

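The data are peak lists from anti-GFP ChIP-seq of CrebA-eGFP in whole wandering larvae, with 1 group of 2 biological replicates labelled 4 and 2. CrebA is known as an activator of genes for the secretory pathway in the embryonic salivary gland. The lists allow 4 questions: how far the replicates share peaks, where the peaks lie, which genes have a peak at the promoter, and which sequences surround the summits. No control immunoprecipitation or second genotype was analysed here.

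The optimal list held 2238 peaks on dm6, of which 2209 were nuclear and 29 mitochondrial. The strongest peaks were mitochondrial, with a top signal of 41179.5 (the authors' units), against 779.8 for the strongest nuclear peak, which 22 of the 29 mitochondrial peaks exceeded. The median signal of all optimal peaks was 111. The nuclear peaks fell on every major arm, with 433 on 2L, 438 on 2R, 499 on 3L, 489 on 3R, 331 on X and 19 on chromosome 4. On dm3 the same reads gave 3699 optimal peaks, 9 of them mitochondrial, with a strongest mitochondrial signal of 2269 and a strongest nuclear signal of 775.

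Of the 2238 strongest peaks of replicate 4, 1323 (59.1%, exact 95% interval 57.0 to 61.2) had a summit within 200 bp of one of the 2238 strongest peaks of replicate 2. After rotation the mean share was 1.23% and the highest 1.92% (one-sided permutation p = 0.000999, the smallest the rotations can give). Of the optimal peaks, 1264 (56.5%) matched the strongest 2238 peaks of both replicates and 122 matched those of neither. Across the 2134 optimal peaks matched in both replicates, Spearman's rho of the signals was 0.456. For the 2110 nuclear ones it was 0.443. These are correlations across peaks, which are not independent replicates, so no p is given. The peaks were in effect chosen by pooled signal, which combines both replicates. That choice can shift rho, so it need not hold for all peaks of the replicates.

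**Figure D1:**
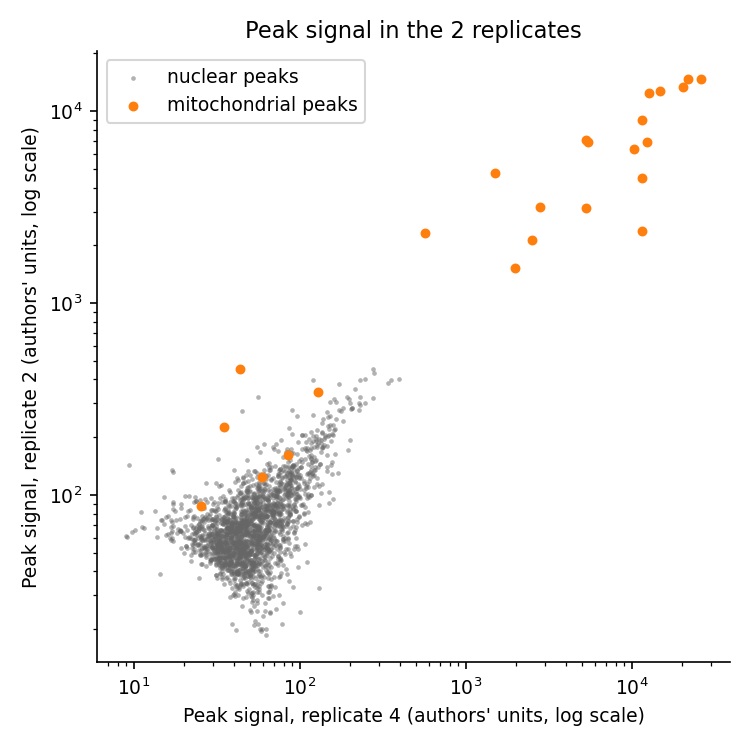
Peak signal in replicate 4 (x axis) and replicate 2 (y axis), both in the authors' units on log scales, for the 2134 optimal dm6 peaks matched within 200 bp in both replicates. Grey points are nuclear and orange points mitochondrial peaks; the strongest mitochondrial peaks stand apart from all nuclear peaks in both replicates.

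Promoters held 920 of the 2238 summits, or 41.1% (95% interval 39.1 to 43.2), which was 2.87 times the mean of rotated peaks (14.3%, one-sided permutation p = 0.000999). Among the other pooled peaks the promoter share was 16.7%, giving an odds ratio of 3.48 for the optimal peaks (95% interval 3.17 to 3.81, Fisher's exact p = 2.84e-148). Introns held 937 summits (41.9%) and intergenic sequence 297 (13.3%). Coding exons held 5 summits (0.223%), against 13.7% of rotated summits. A promoter peak was found at 718 of 13981 protein-coding genes (5.14%), including 11 of the 13 mitochondrial genes.

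**Figure D2:**
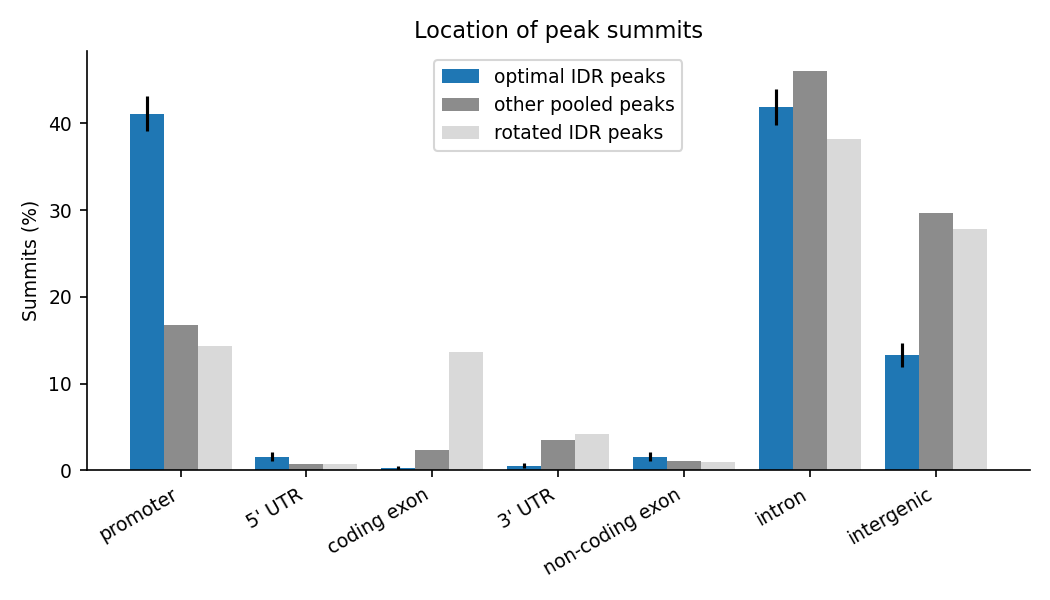
Share of summits (%, y axis) in each annotation class (x axis) for the 2238 optimal peaks (blue, bars are Wilson 95% intervals), the 27761 other pooled peaks (dark grey) and rotated optimal peaks (light grey, mean of 20 rotations). Optimal peaks lie at promoters in 41.1% of cases, against 16.7% and 14.3%.

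The 10 protein-coding genes with the strongest promoter peaks were all mitochondrial: mt:CoI, mt:ATPase6, mt:ATPase8, mt:ND3, mt:CoII, mt:Cyt-b, mt:ND1, mt:ND2, mt:ND4 and mt:ND4L. Their signals ran from 5718.5 at mt:ND4 to 41179.5 at mt:CoI. Several shared one long peak: a single interval from position 1 to 6074 of the mitochondrial genome carried the summits of mt:CoI, mt:ATPase6, mt:ND3, mt:CoII and mt:ND2. Optimal peaks covered 90.6% of that genome. A promoter peak there means only a summit within 500 bp of an annotated gene start, not a site at a promoter. Among nuclear genes, the strongest promoter peak (2R 18411803 to 18412185, signal 618) lay 33 bp from a start site of Dp1 (FBgn0027835), which encodes a KH-domain RNA-binding protein, and 462 bp from one of imd (FBgn0013983), the adaptor of an innate immune pathway. It was followed by Gapdh2, a glycolytic enzyme (X 15867816 to 15868149, signal 555), CG1888 (552) and Tapdelta, a subunit of the translocon-associated complex of the endoplasmic reticulum (2R 11371000 to 11371309, signal 525). Next came the Polycomb group gene ph-p (524), larp (518), Syp (494), the JNK phosphatase gene puc (491) and Hsc70-3, the BiP chaperone (X 11805269 to 11805767, signal 467).

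Genes of the early secretory pathway carried promoter peaks more often than other genes. Of 79 members, 13 had one (16.5%, 95% interval 9.88 to 26.1), against 5.07% of the 13902 other protein-coding genes (odds ratio 3.69, 95% interval 1.86 to 6.79, Fisher's exact adjusted p = 0.000945). With replicate 4 alone 15 of the 79 had one (odds ratio 4.19) and with replicate 2 alone 20 did (5.55). The odds ratio was 6.11 with the 1119 strongest peaks. Among genes with any pooled peak at the promoter, 13 of 16 early secretory genes had an optimal one (odds ratio 15.9, 95% interval 4.35 to 87.2). That ratio leaves out the members without a pooled peak and compares peak strength among genes that have one. Most of the 13 came from the joint list for N-glycosylation and folding in the endoplasmic reticulum. There 7 of 24 genes had a peak (29.2%, odds ratio 7.67, Fisher's exact adjusted p = 0.000945). These 7 were led by Hsc70-3, the peptidyl-prolyl isomerase gene Fkbp14 (2R 21497191 to 21497501, signal 350) and the protein disulphide isomerase gene ERp60 (2R 11890880 to 11891109, signal 289). The ERp60 peak also lay 160 bp from a start site of eEF1alpha1, a translation elongation factor gene outside the housekeeping lists. The chaperone genes Calr and Cnx99A had none. Nor did any of the listed oligosaccharyltransferase genes Dad1, OstDelta, Ostgamma, Ost48, Stt3A and Stt3B. The peaks of this list thus lay outside that enzyme of N-glycosylation. Of the 20 genes for entry into the endoplasmic reticulum, 4 had a peak (20%, odds ratio 4.64), which missed the threshold (Fisher's exact adjusted p = 0.0554). The list passed at 250 bp (Fisher's exact adjusted p = 0.0303), with the 1119 strongest peaks (0.00955) and with replicate 2 alone (0.00304), and not at 1000 bp (0.0878), with replicate 4 alone (0.0629), with gene 5′ ends (0.154) or against lists matched on start sites (permutation, adjusted p = 0.0858). The 4 were Tapdelta, the translocon channel gene Sec61alpha (2L 6480258 to 6480602, signal 355), the signal peptidase gene Spase25 (199) and Trp1 (171). Sec61beta, Sec61gamma and Sec63 had none. Of 35 genes for vesicles between the endoplasmic reticulum and the Golgi, 2 had a peak (5.71%, Fisher's exact adjusted p = 0.701): the COPII coat gene Sec24CD (2L 2236811 to 2236991, signal 263) and loj (79.9). With replicate 4 alone 4 had one (odds ratio 2.28) and with replicate 2 alone 5 did (2.68), against 1.12 for the optimal list, neither past the threshold (Fisher's exact adjusted p = 0.266 and 0.108). The members alphaCOP, Arf1 and bai had none. Of the 15 genes of the unfolded protein response and of degradation from the endoplasmic reticulum, 2 had a peak (Fisher's exact adjusted p = 0.317), both encoding bZIP factors: Xbp1 (2R 21143423 to 21143715, signal 395) and crc (199). No peak of the relaxed replicate 4 list matched the one at Xbp1. The secretory lists overlap the early secretory list by construction and are not independent of it.

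The housekeeping lists, mostly genes active in most cells, carried promoter peaks less often than early secretory genes. Of the 200 proteasome, ribosome and respiration genes, 6 had one (3%, 95% interval 1.38 to 6.39), against 13 of the 79 early secretory genes (odds ratio 6.32, 95% interval 2.14 to 21.1, Fisher's exact p = 0.000197). The 200 include paralogues that need not be broadly active; without the 37 with paralogue symbols, 6 of 163 had a peak (odds ratio 5.11, 95% interval 1.73 to 17.1, Fisher's exact p = 0.00135). With replicate 4 alone the odds ratio over all 200 was 11.4 and with the 1119 strongest peaks no housekeeping gene had a promoter peak. They were 0 of 32 proteasome genes, 5 of 86 ribosomal protein genes and 1 of 82 respiration genes. The strongest were ND-B14.5B (93.9), RpS30 (83.0), RpS3A (82.9) and RpS21 (79.0). Among genes with a peak, the median signal was 239 for the 13 secretory genes and 80.9 for the 6 housekeeping genes (two-sided exact permutation p = 0.00361). It was 117 for all 694 nuclear genes with a peak outside the early secretory list, the 6 housekeeping genes included (permutation p = 0.00014 against the secretory genes). That last comparison, which leaves out mitochondrial genes, was not in the plan.

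Of the genes of the ecdysone response, the steroid hormone that drives the end of larval life, 8 of 17 had a promoter peak (47.1%, 95% interval 26.2 to 69.0, odds ratio 16.6, 95% interval 5.55 to 48.6, Fisher's exact adjusted p = 1.2e-05). The strongest were at EcR, the ecdysone receptor (2R 6132049 to 6132251, signal 378), the ETS factor gene Eip74EF (3L 17576387 to 17576790, signal 282) and Kr-h1 (2L 6082174 to 6082577, signal 191). The genes of this list had 3.24 distinct start sites on average, against 1.40 for all protein-coding genes. When only the 5′ end of each gene was used, the odds ratio was 3.38 and the test was not passed (Fisher's exact adjusted p = 0.27). Against random lists matched on start sites, the count was 2.82-fold higher (two-sided permutation, adjusted p = 0.0139).

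No cuticle gene had a promoter peak (0 of 121, upper 95% limit 3.08%, Fisher's exact adjusted p = 0.0119), a lower share than that of other genes. Among salivary gland genes, 2 of 12 glue genes had one (Fisher's exact adjusted p = 0.261), namely Sgs5 (114.9) and Sgs1 (77.7). The odds ratio of 3.70 fell to 1.60 with replicate 4 alone and 1.46 with replicate 2 alone, where in each case 1 glue gene had a peak. Of 12 regulators of that gland, 3 had one (25%, odds ratio 6.18, Fisher's exact adjusted p = 0.0559): the homeotic gene Scr (104), the forkhead gene fkh (98.1) and trh (89.3). The regulators passed at 1000 bp (Fisher's exact adjusted p = 0.0182) and with replicate 2 alone (0.0127), and not with replicate 4 alone (0.0629). At 250 bp 1 of them had a peak (odds ratio 2.16, Fisher's exact adjusted p = 0.552), and with the 1119 or the 1000 strongest peaks 0 did. Muscle genes had a peak in 2 of 20 cases, at Mef2 (184) and Zasp52 (88.4). Neuronal genes had 1 of 16 (Syt1, 87.8), fat body genes 1 of 12 (Lip4, 77.3) and tracheal and gut genes 1 of 14 (Mur29B, 88.5). The tracheal and gut list lacks the unmatched name dp, whose peak status was therefore not counted. None of those 4 tissue lists passed the test (adjusted p from 0.439 to 0.651). The cuticle result ended with the 1119 strongest peaks (Fisher's exact adjusted p = 0.169), at 250 bp (adjusted p = 0.0526) and against lists matched on start sites (permutation, adjusted p = 0.0858), as it did with the 1000 strongest peaks and with gene 5′ ends. The count of 0 could not change in these settings. Where it could rise, it was 0 at 1000 bp and with replicate 4 alone, and 1 of 121 with replicate 2 alone (odds ratio 0.133, Fisher's exact adjusted p = 0.0275).

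**Figure D3:**
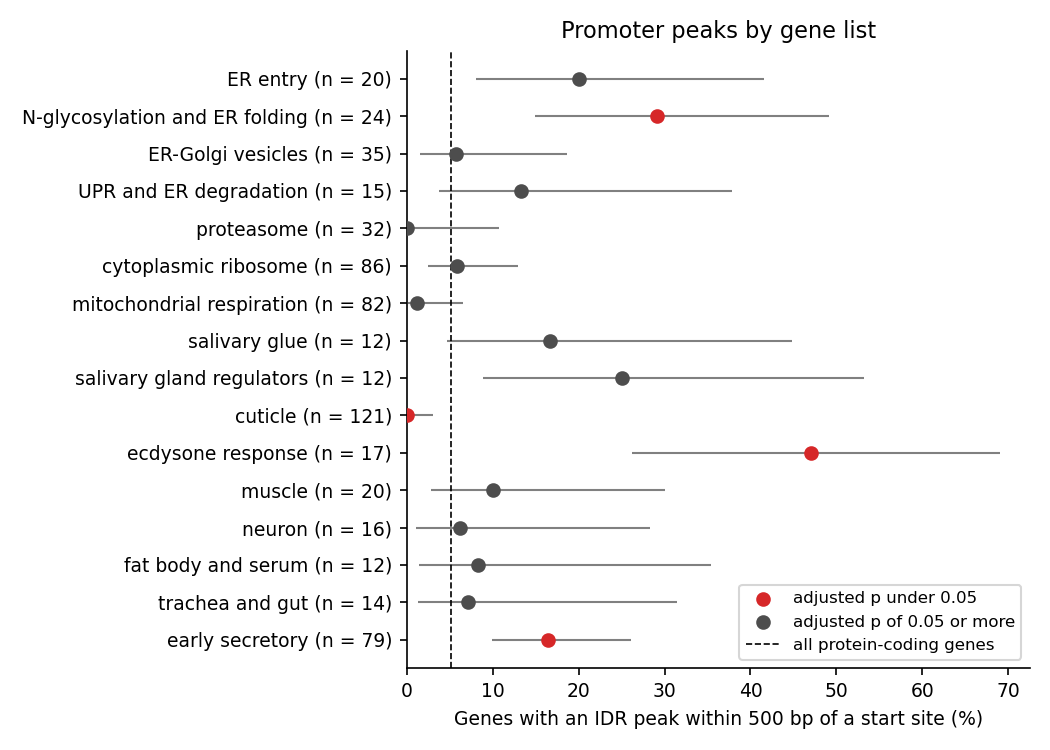
Share of genes (%, x axis) with an optimal peak within 500 bp of a start site, for each gene list (y axis, n is the number of members), with Wilson 95% intervals as lines. Red points passed an adjusted p of 0.05; the dashed line marks all protein-coding genes (5.14%). Ecdysone response, N-glycosylation and ER folding and early secretory genes lie above it, and cuticle genes below.

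The CrebA gene itself (FBgn0004396, 3L 15535395 to 15553214, plus strand) had no peak within 500 bp of its annotated start site. It had 4 optimal peaks within 5000 bp of the gene. The strongest lay in an intron (3L 15547390 to 15547793, signal 186, rank 333 of the optimal list, ranks 304 and 537 in replicates 4 and 2). The other three had summits 879, 1718 and 2965 bp upstream of the start site, with signals of 94.2, 124 and 128.

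The 8-base site of the CREB3 family, CCACGTCA, was rare at summits. It occurred within 100 bp of 6 of 2234 summits (0.269%, 95% interval 0.123 to 0.585), against 0.425% of the flanking windows (ratio 0.632, exact McNemar p = 0.607). The ratio ran from 0.4 to 1.38 under the alternatives that kept this site, none of them past the threshold. Its 7-base core CACGTCA gave 1.39% against 1.19% (exact McNemar adjusted p = 1). The GAGA factor sequence GAGAG had the smallest p of the 12 motifs, at 881 summits (39.4%) against 25.2% of flanks (ratio 1.57, exact McNemar adjusted p = 6.05e-24). The forkhead sequence TGTTTAC (6.31% against 4.25%, exact McNemar adjusted p = 0.0288), the GATA sequence AGATAA (15.1% against 12.2%, adjusted p = 0.0495) and ACGTG (19.3% against 15.7%, adjusted p = 0.0495) were also above the flanks. With windows of 50 bp GAGAG passed (ratio 1.44) and these last 3 missed the threshold (exact McNemar adjusted p = 0.147, 0.0629 and 0.147). Their ratios did not fall: they were 1.55, 1.33 and 1.26, against 1.48, 1.23 and 1.23 at 100 bp, with fewer summits holding a site (75, 193 and 232, against 141, 337 and 431). The ratio was higher than that of GAGAG for the DRE sequence (1.90), which rested on 19 summits and did not pass (exact McNemar adjusted p = 0.905). The CRE, E-box, AP-1, DRE, Zelda and M1BP sequences did not differ from the flanks past the threshold (adjusted p from 0.905 to 1). Among 2055 6-base sequences ranked by the ratio of summit to flank, GAGAGC came first (2.24) and AGAGAG next (2.15).

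**Figure D4:**
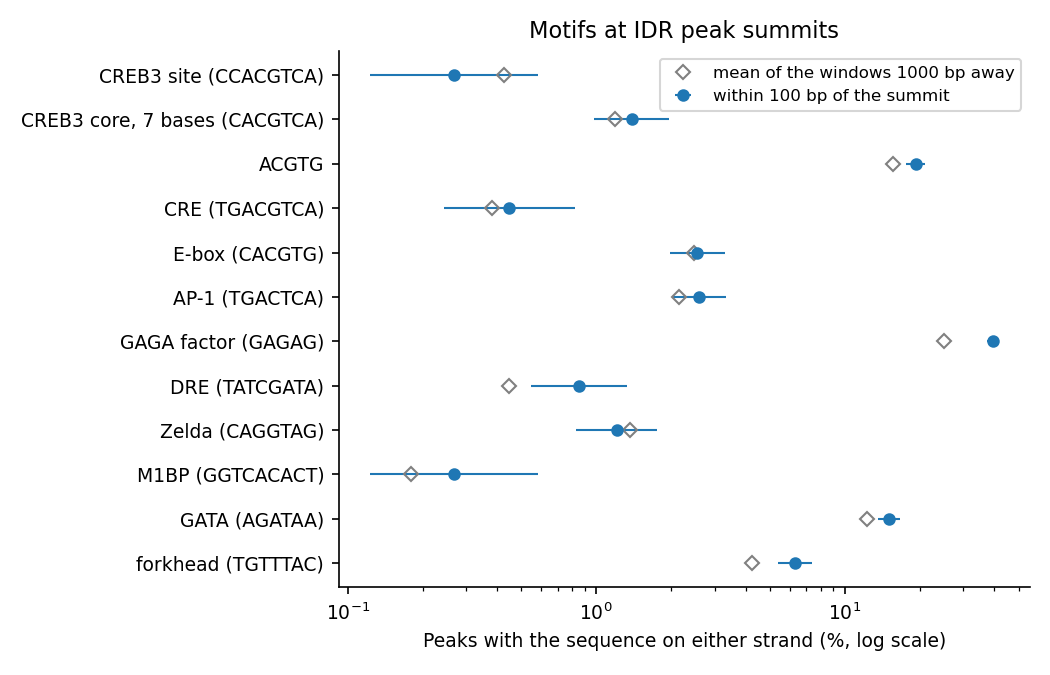
Share of the 2234 summits (%, x axis, log scale) with each motif (y axis) on either strand within 100 bp (blue circles, lines are Wilson 95% intervals) and the mean share in windows 1000 bp to either side (open diamonds). GAGAG rises from 25.2% to 39.4%, while CCACGTCA is at 0.269% against 0.425%.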

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

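Both tests of the mitochondrial peaks were chosen after the result was seen.

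On dm3, 9 optimal peaks lay on Uextra, sequence that this assembly leaves unplaced. They count among the 3699 dm3 peaks above but enter no gene or motif comparison, which use dm6, and are given as data left unanalysed.

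The strongest dm6 peaks lay on the mitochondrial genome. Peaks covered 90.6% of its length in the optimal list, 80.6% in replicate 4 and 89.6% in replicate 2, as a blanket of signal would and separate sites would not. The strongest mitochondrial signal on dm6 was 18.1 times that on dm3, where optimal peaks covered 2531 bp of it against 17694 bp on dm6, while the median of the 100 strongest nuclear peaks changed by a factor of 0.954. Much of that signal may therefore come from the amount of mitochondrial DNA and from reads handled differently on the 2 assemblies, for instance reads shared with copies elsewhere. The same reads were used on both assemblies, so the amount of mitochondrial DNA cannot account for the difference between them. How far it accounts for the signal on dm6 stays open, as does whether the control differed, and no biological explanation was tested.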

How the results depend on the processing

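Tests without mitochondrial peaks, without housekeeping paralogues, within the span of pooled peaks, against lists matched on start sites, and, for single lists, with the 1000 strongest peaks or gene 5′ ends were chosen after the data were seen. The replicate overlap (52.7 to 62.2%), the promoter share (28.5 to 54.1%), the early secretory enrichment (odds ratio 3.42 to 15.9, or 3.25-fold over matched lists) and the secretory against housekeeping difference (odds ratio 5.11 to 11.4 where it could be computed) kept their direction and their side of the threshold under every alternative run. The 15.9 covers only the 16 early secretory genes with any pooled peak at the promoter. With the 1119 or the 1000 strongest peaks no housekeeping gene had a promoter peak, so the odds ratio against housekeeping genes has only a lower 95% limit, 7.95 and 7.08. The cause of the changes below was not tested. The peak count was 1119 for the stronger peaks and 3699 on dm3.

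With the 1119 strongest peaks the odds ratio was 8.39 for ER entry (now past the threshold), 0.978 for ER-Golgi vesicles, and 0 for ribosome, salivary regulator, cuticle, neuron, fat body, and trachea and gut genes. With the 1000 strongest it was 9.36 for ER entry (past it) and 0 for the ribosome, glue, salivary regulator, cuticle, neuron, fat body, and trachea and gut lists. At 250 bp it was 5.98 for ER entry (past it) and 0 for cuticle (no longer past it). At 1000 bp it was 0.874 for ER-Golgi vesicles, 0.962 for neuron and 7.24 for salivary regulators (past it). With gene 5′ ends it was 3.38 for ecdysone response and 0 for cuticle, both no longer past it, 0 for neuron and 0 for fat body, and 1 list besides the early secretory one passed, against 3. Over lists matched on start sites the fold was 0.845 for ribosome, 0.601 for muscle, 0.44 for neuron, 1.00 for fat body and 0 for cuticle (no longer past it).

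With each replicate alone, 3 to 5 lists besides the early secretory one passed, and so did the early secretory list. Odds ratios ran from 4.19 to 5.55 for the early secretory list (15 and 20 of 79 genes, against 13 and 3.69), and from 4.42 to 6.92 for ER entry and 5.89 to 8.06 for salivary regulators, these last 2 lists past the threshold with replicate 2 alone. They ran from 0.418 to 1.21 for ribosome, 0 to 1.46 for fat body and 0.845 to 1.96 for muscle. Among lists that stayed on their side, they ran from 2.28 to 2.68 for ER-Golgi vesicles, 1.46 to 1.60 for glue, 1.26 to 4.02 for UPR genes and 1.07 to 2.52 for neuron. For respiration the odds ratio was 0.439 with replicate 4 alone (2 of 82) and 0.197 with replicate 2 alone (1 of 82), against 0.227. The CREB3 site ratio ran from 0.857 to 1.38. It was 1.09 with the 1119 strongest peaks, 1.20 against shuffled windows, 1.17 for CACGTCA and 1.23 for ACGTG. With 50 bp motif windows 1 motif passed, against 4, while the ratios of the other 3 did not fall: 1.55 for forkhead, 1.33 for GATA and 1.26 for ACGTG, against 1.48, 1.23 and 1.23. No paired analysis was possible because the series has a single group.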

Other observations

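The start-site matching, housekeeping paralogue, ACGTG, tRNA, non-coding gene and missing-peak tests were chosen after the data were seen. The housekeeping test was planned, and its reading as a test of an explanation came after the list counts were seen. The GAGAG tests were set before their results were seen.

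Transfer RNA genes, transcribed by RNA polymerase III, had summits nearby more often than after rotation. Of 290 nuclear tRNA genes, 53 (18.3%) had an optimal summit within 200 bp of the start. These were 41 summits, or 1.86% of nuclear peaks, against 0.0794% after rotation (23.4-fold, one-sided permutation p = 0.000999, the smallest possible). Long non-coding and other ncRNA genes had 57 such summits (2.96-fold, permutation p = 0.000999), snoRNA genes 1 (p = 0.734) and snRNA genes 1 (p = 0.193).

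Early secretory promoters carried peaks more often than other promoters. Peaks at any broadly active promoter would give housekeeping genes a like share, and the odds ratio of 6.32 against them (95% interval 2.14 to 21.1), or 5.11 (1.73 to 17.1) without their paralogues, argues against that as the whole cause. The housekeeping lists do not hold every such gene: the peak at ERp60, among the 13, also lay at eEF1alpha1, which is in none of them. Their share of 3% was also below the 5.14% of all protein-coding genes. They therefore cannot stand for every promoter open to unspecific signal. Such signal was not tested, as no GFP or input control was analysed here. The number of start sites is argued against by its mean, 1.37 for early secretory genes and 1.40 for all protein-coding genes. With means so alike, the 3.25-fold excess over matched lists (two-sided permutation p = 0.0008) largely restates the enrichment over all genes. ACGT core sites stay open as an explanation. ACGTG lay within 100 bp of 10 of the 13 secretory promoter peaks and 142 of 638 other nuclear promoter peaks (odds ratio 11.6, 95% interval 2.93 to 66.4, Fisher's exact p = 5.56e-05), but while ACGTG was among the motifs fixed beforehand, this comparison was chosen after several short sequences had been looked at in these same secretory peaks, so it restates what was noticed and is no support for the explanation. Of the other motifs compared there, CACGTCA gave 4 of 13 against 13 of 638 (Fisher's exact p = 0.000198), the full CREB3 site CCACGTCA 1 of 13 against 3 of 638 (p = 0.0777, not past the threshold) and GAGAG 6 of 13 against 314 of 638 (p = 1).

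GAGAG had the smallest p of the motifs at summits, with a ratio of 1.57 to the flanks. Summit windows shuffled so as to keep their dinucleotides held GAGAG in 20.7% of cases, 1.91-fold fewer than the real ones (exact McNemar p = 1.64e-53). Such a shuffle breaks up GA repeats wherever they lie. The unshuffled flanks, at 25.2%, were also above the shuffled share, and the flanks themselves were not shuffled. The test therefore cannot decide whether base composition of the windows is the cause, which stays open. Promoter sequence as the whole cause is argued against by the ratio of 1.29 among the 1316 peaks outside promoters (exact McNemar p = 3.98e-05), though the ratio was 2.02 among the 918 promoter peaks. Sequence shared by open chromatin at active regions was not tested, and a GFP or input control, which would bear on it, was not analysed here. The motif therefore may mark accessible regions as well as sites of the tagged factor.

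Of the 2209 nuclear optimal dm6 peaks, 41 had no summit within 1000 bp in the relaxed list of replicate 4 and 0 in that of replicate 2. On dm3 the counts were 54 and 8 of 3681. On dm6, 8 of those 41 were among the 300 strongest nuclear peaks. A place in the optimal list therefore did not require a summit within 1000 bp in the relaxed list of each replicate.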
